A study of Strongylocentrotus purpuratus with 4 samples.

How the data were processed

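Polyadenylated RNA was sequenced from whole larvae of the purple sea urchin Strongylocentrotus purpuratus at 4 times: before exposure (0 h) and after 6, 12 and 24 h in the presence of Vibrio diazotrophicus, a marine bacterium. Per the labels, each library came from a pool of larvae of a single mating, the larvae were fed a unicellular alga, and libraries were made for the SOLiD platform. The larvae of the first 3 libraries were labelled 9 days post fertilization and those of the 24 h library 10 days. There was 1 library per time, so no value has a spread between replicates, and no unexposed library of a later time was analysed here.

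The authors deposited 1 table with an expression signal per gene model and library, given to 2 decimals. Per the file headers, its columns are an SPU gene identifier, a gene family code and the 4 times, and every value column was matched to its sample by the time in its name. Bowtie 0.12.7 is named in the submitters' processing notes. The genome build, the gene models, the counting, the treatment of reads that match several genes and the unit of the deposited signal are not given in the sources used here. The values are fractions, their totals per library lie between 455921 and 506750, and the smallest values above 0 differ between genes, as in read numbers divided by gene length. They were therefore treated as normalized values, named levels below, and not as counts.

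The SPU identifiers carry no gene names in the table, and 0 of them matched the 33503 genes of the reference table for assembly Spur_5.0. The 35 gene lists fixed before the data were examined, which held name patterns for cytokines, immune receptors, signalling, effectors, stress genes and markers of larval cell types, could not be applied. The planned list procedure was run instead on the family codes of the deposited table, a choice made after the data were examined. By the rule fixed for a table without names, only 2 identifiers with higher and 2 with lower levels are printed: those with the highest and the lowest log2 ratios over the 3 comparisons among genes with a level of at least 5 in 1 of the libraries compared. Taking the 3 comparisons together for this pick was decided after their values were seen, as were the comparisons of the genes so found in the libraries not used to find them. Other genes are described by rank and level.

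Each of the 3 exposed libraries was compared with the 0 h library as log2 of (level + 1) over (0 h level + 1), a scale that understates the change of genes near or under a level of 1. A gene was measured in a comparison if its level was at least 1 in at least 1 of the 2 libraries. Genes at least 2-fold and 4-fold apart on that scale were counted. For a comparison of 2 single libraries, no test, p-value or standard error across samples can be given, and no trend over the 4 times was tested. The time of the highest level was taken for genes whose highest library was at least 4-fold over the lowest. For each family code with 3 or more measured members, the median log2 ratio was placed among the medians of 10000 random lists of uncoded genes of the same size, matched on mean log2 level in 20 bins. These percentiles describe these libraries and are not p-values. The alternatives were pseudocounts of 0.1 and 5, no floor and a floor of 5, a 4-fold threshold, scaling by median-of-ratios or by the upper quartile, and random lists without matching. Upper-quartile scaling of the families and of the time of highest level was added after the data were examined.

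Total read numbers are not given in the sources used here, so the depth is unknown in absolute terms and no counting interval can be given. Relative depth was estimated from low genes, on the unchecked assumption that their levels are whole multiples of what 1 read is worth. The ratio of read worth that best explained the levels of such genes was 0.947 for the 0 h over the 6 h library (278 genes), 1.01 for 0 h over 12 h (338 genes) and 0.763 for 0 h over 24 h (361 genes). The direct estimate for 12 h over 24 h was 0.766, against 0.757 through the 0 h library. Apart from the best ratio, the score was read only near 2 times that ratio, where whole multiples can fit again. For 0 h over 24 h its gain over the median score was 59.8 at 1.53, against 97.3 at 0.763. The 24 h library, however, had the fewest genes at 0 (2716, against 3100 at 0 h). It also had the most genes above 0 in that library only (252, against 135). Whether the 24 h library was deeper or shallower than the 0 h library is therefore not settled. The estimate was added after the data were examined. Genes above 0 in 1 library only had a median level of 0.04 at 0, 6 and 12 h and 0.03 at 24 h, and a 95th percentile between 0.144 and 0.173. Such levels rest on few reads, and what 1 read is worth differs between genes.

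The procedures were tested on simulated data: a simulated library against the 0 h library, with noise of 0.1 on the log2 scale and 18087 genes measured. Of 50 genes planted at each fold, 0 were called at 1.5-fold, 50 at 3-fold, 50 at 8-fold and 50 at a fold of 0.125, and 0 of 17887 unchanged genes were called. Lists of 15 genes shifted by 0.5 lay above the 97.5th percentile in 100% of 50 draws and unshifted lists in 4%. With so little noise an unchanged gene cannot be expected to reach 2-fold, so the calls and the recovery of shifted lists only check the computation. They do not give error rates for the real libraries, whose noise is not known. The quartiles of the log2 ratio over measured genes at 6 h were -0.11 and 0.27, wider than the simulated noise. Computation used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.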

Results

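Sea urchin larvae live in water rich in bacteria, and the study followed their transcript levels over 24 h of exposure to Vibrio diazotrophicus. The table held 29125 gene models in 4 libraries: 1 of unexposed larvae (0 h) and 1 each after 6, 12 and 24 h. The levels summed to 455921 at 0 h, 506750 at 6 h, 486324 at 12 h and 494120 at 24 h. A level of at least 1 was reached by 17991 gene models at 0 h, 18180 at 6 h, 18311 at 12 h and 18730 at 24 h, while 1690 were listed at 0 in all 4 libraries. The 10 highest genes took between 7.22% and 7.88% of the total in each library. Each time was represented by a single library, so differences below are differences between libraries, with no replicate check.

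The first comparison asked which genes differed after 6 h of exposure. Of 18608 measured genes, 270 were at least 2-fold higher at 6 h than at 0 h and 46 were at least 2-fold lower, together 1.70% of those measured. The 4 genes with the highest ratios had nearly the same levels as each other throughout: 0.15 to 0.21 at 0 h, 13.97 to 18.07 at 6 h, 3.48 to 4.13 at 12 h and 3.57 to 4.13 at 24 h. Their levels at 0 h are close to those of genes seen in a single library (95th percentile 0.173 at 0 h) and rest on few reads, so the size of their ratio is uncertain. Near-identical copies of a gene can share reads, and such genes are then not separate measurements. The gene at rank 6 was the most abundant of the top 8, with levels of 20.21 at 0 h, 253.46 at 6 h, 347.08 at 12 h and 142.11 at 24 h. At the other end, SPU_015358 had a level of 71.71 at 0 h and 9.29 at 6 h (log2 ratio -2.82), with 8.22 at 12 h and 11.36 at 24 h. SPU_002251 had a level of 9.51 at 0 h and 0.76 at 6 h (log2 ratio -2.58). It stood at 1.30 at 12 h and at 8.86 at 24 h, close to its 0 h level. With median-of-ratios scaling the counts at 6 h were 215 higher and 68 lower, so the share of higher genes among those 2-fold apart went from 85.4% to 76.0%, and it was 73.1% with upper-quartile scaling.

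After 12 h the number of genes at least 2-fold from the 0 h level was larger in both directions: 1008 genes were higher and 267 lower, out of 18870 measured. At least 4-fold differences were found for 121 higher and 12 lower genes, against 21 and 2 at 6 h. The top of the list held abundant transcripts. SPU_022144 had a level of 24.77 at 0 h, 61.25 at 6 h and 437.54 at 12 h (log2 ratio 4.09), a ratio of levels of 17.7, and 438.91 at 24 h. The genes at ranks 3 and 4 had nearly the same ratios at lower levels, with 12.37 and 11.71 at 0 h and 216.26 and 198.87 at 12 h. The gene at rank 5 had levels of 39.54 at 0 h, 553.86 at 12 h and 92.48 at 24 h. Among the genes with the lowest ratios, 4 were among the abundant transcripts of unexposed larvae: their levels lay between 1371.74 and 1656.40 at 0 h, between 542.73 and 738.69 at 6 h and between 229.47 and 295.91 at 12 h, and were 328.93 to 416.88 at 24 h. As at 6 h, genes with nearly the same course and levels may share reads and are then not separate measurements. With median-of-ratios scaling 849 genes were higher and 406 lower at 12 h, which put the share of higher genes at 67.6% instead of 79.1%, and upper-quartile scaling put it at 60.7%.

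At 24 h, 1209 of 19142 measured genes were at least 2-fold higher than at 0 h and 305 were at least 2-fold lower. The balance between both directions depended on the scaling: 633 genes were higher and 645 lower with median-of-ratios scaling, and 586 and 705 with upper-quartile scaling. The median log2 ratio of all measured genes was 0.22 at 24 h as deposited, against 0.07 at both 6 h and 12 h, and it was -0.01 at each time after median-of-ratios scaling. The level of SPU_022144 was 17.7 times its 0 h level, and SPU_012743 had levels of 1.84 at 0 h, 11.54 at 6 h, 30.54 at 12 h and 46.78 at 24 h, a log2 ratio of 4.07. The gene at rank 5 had 7.01 at 0 h, 33.14 at 12 h and 99.51 at 24 h, and the gene at rank 7 had 15.39, 120.78 and 170.77. Among the lower genes, that at rank 2 had levels of 59.75, 44.04, 22.73 and 11.72 at 0, 6, 12 and 24 h, and that at rank 4 had 44.67, 35.61, 15.95 and 9.11. The larvae of this library were also labelled 1 day older than the others, so exposure time and age go together in this comparison.

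**Figure D1:**
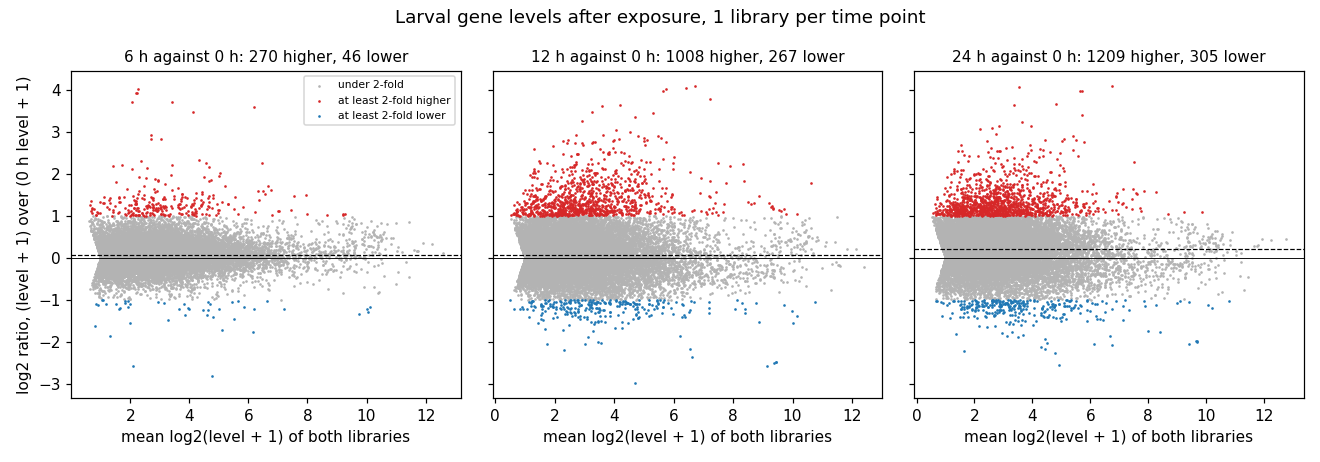
Log2 ratio of each exposed library to the 0 h library, on the (level + 1) scale, against the mean log2(level + 1) of both libraries, for every measured gene; red and blue points are at least 2-fold higher and lower, and the dashed line is the median of all measured genes. The 24 h panel is shifted upward, with a median of 0.22.

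**Figure D2:**
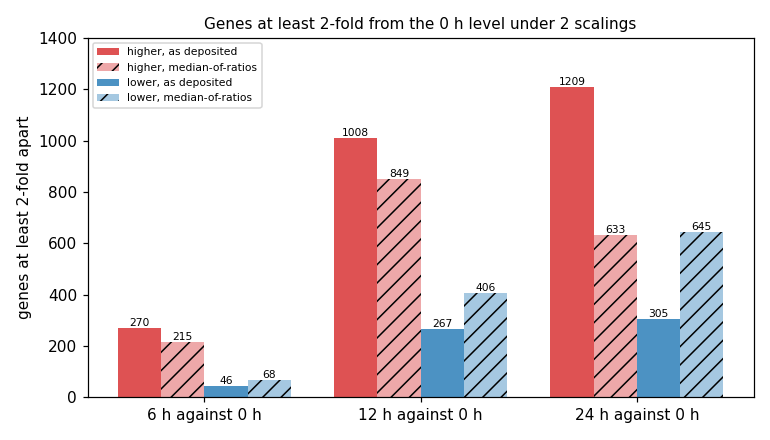
Number of genes at least 2-fold from the 0 h level at 6, 12 and 24 h, with the levels as deposited (solid bars) and after median-of-ratios scaling (hatched bars). At 24 h the 1209 higher and 305 lower genes become 633 and 645 after scaling.

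The course over time was described with genes whose highest library was at least 4-fold over the lowest. There were 193 such genes, and the lowest library was 0 h for 155 of them. The highest level was reached at 12 h by 105 genes, at 24 h by 62, at 0 h by 17 and at 6 h by 9. The order of 12 and 24 h depended on the pseudocount, with 241 genes highest at 12 h and 249 at 24 h for a pseudocount of 0.1, and the number highest at 24 h was 35 under either scaling. The level was higher in each later library for 41 genes and lower in each later library for 6. Genes picked by 1 comparison were then followed in the 2 libraries that the comparison did not use. The 270 genes that were 2-fold higher at 6 h had a median log2 ratio of -0.35 for 24 h over 12 h, where the median of all measured genes was 0.12, and 45 of them were at least 2-fold lower at 24 h than at 12 h while 1 was at least 2-fold higher. The 46 genes that were lower at 6 h had a median of 0.42 in the same libraries. After median-of-ratios scaling those medians were -0.50 and 0.27, against -0.02 for all measured genes. In the 1008 genes that were higher at 12 h, the median for 24 h over 6 h was 0.37 and 756 genes were above 0. The median of all measured genes there was 0.12. In the 267 genes that were lower at 12 h the median was -0.50, and scaling gave 0.22 and -0.64 for these 12 h sets. In the 1209 genes that were higher at 24 h, the median for 12 h over 6 h was 0.51 and 1113 genes were above 0, while the median of all measured genes was 0.00. In the 305 genes that were lower at 24 h that median was -0.60, and scaling gave 0.51 and -0.61 for these sets.

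The table gives 462 gene models 1 of 31 family codes. Roman numerals with letters and names such as Short, Orphan, Fly-like and Intron containing are in use for groups of the Toll-like receptors of this species, a large family of innate immune receptors. The table does not say which genes its codes stand for, and they are kept here as given. Coded genes were mostly low: a level of at least 1 in any library was reached by 82 of the 186 genes with a number as code and by 33 of the 276 with a letter code, or 44.1% and 12.0%, against 67.3% of uncoded genes. Of the coded genes, 8 were at least 2-fold higher at 1 or more times and 0 were at least 2-fold lower at any time. Under either scaling 7 of the 8 were still 2-fold higher. All but 1 of these 8 had levels under 1 at 0 h. Most coded genes were under 1 at 0 h, and on this scale such genes cannot be 2-fold lower. This does not hold for families 6, 7 and 8.3, whose lowest levels at 0 h were 1.37, 2.01 and 1.31. Why no coded gene was 2-fold lower was not tested, and few of all measured genes were. At 24 h, 3 of 81 measured genes with a number as code and 4 of 32 with a letter code were 2-fold higher. Of all measured genes, 6.32% were 2-fold higher at 24 h and 1.59% were 2-fold lower. Values of family members can share reads where copies are near-identical, and how such reads were counted is not given in the sources used here.

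Families 7 and 6 held the most abundant coded genes, and every member was above its 0 h level at each time, except that 2 of the 18 members of family 6 were not at 6 h after either scaling. In family 7, with 22 members, the median level was 10.9 at 0 h, 14.8 at 6 h, 17.9 at 12 h and 20.4 at 24 h. Its median log2 ratio was 0.42 at 6 h, 0.69 at 12 h and 0.85 at 24 h, with an SD over members of 0.073 at 24 h. Those medians lay at percentiles of 99.99, 100 and 100 among the random lists, whose own median at 24 h was 0.24. In family 6, with 18 members, the median level was 6.01 at 0 h and 10.8 at 24 h, and the median log2 ratio was 0.25 at 6 h, 0.51 at 12 h and 0.77 at 24 h, at percentiles of 97.48, 99.8 and 100. The random lists hold separate genes, so these percentiles are too extreme in both families if members share reads and move as 1 measurement. Among single measured genes at 24 h, the upper quartile of the log2 ratio was 0.54, and 6.32% were at least 2-fold higher. After median-of-ratios scaling all 22 members of family 7 were still above 0 at each time, with a median of 0.59 at 24 h, and the median of family 6 was 0.53 at 24 h. A difference of 2-fold was reached by 1 member of family 7 at 24 h (7.43 to 15.96, log2 ratio 1.01) and by 0 members of family 6. That member was under 2-fold after either scaling, with log2 ratios of 0.76 and 0.73.

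**Figure D3:**
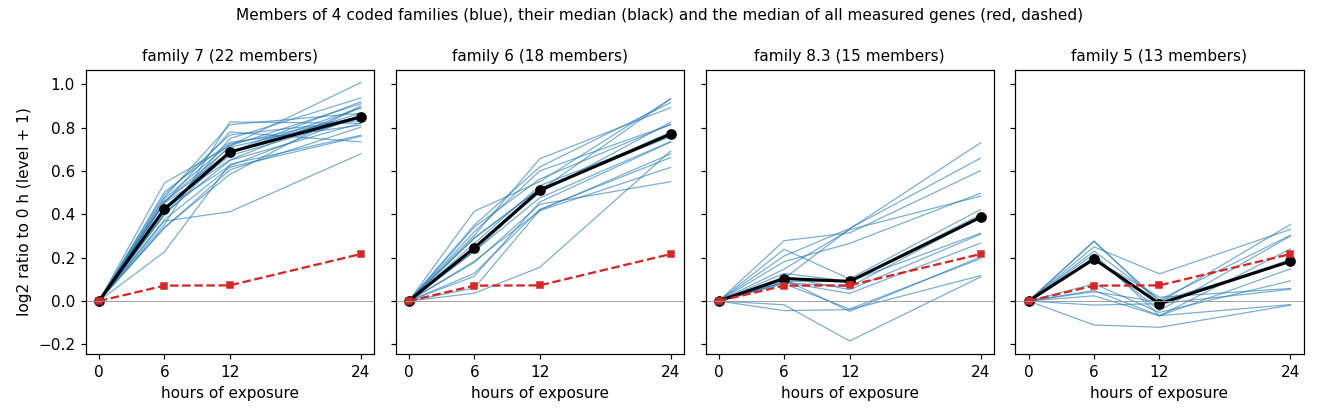
Log2 ratio to 0 h on the (level + 1) scale for the members of families 7, 6, 8.3 and 5 with a level of at least 1 in any library, against hours of exposure; blue lines are members, black their median, and the dashed red line the median of all measured genes. Members of families 7 and 6 lie above the red line at 24 h, while the median of family 5 does not.

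Among other families with a number as code, the number of measured members and the direction varied. In family 8.3 all 15 members were measured, with median log2 ratios of 0.10, 0.09 and 0.39 at 6, 12 and 24 h, at percentiles of 79.3, 57.5 and 90.5. The 6 h value was 0.04 after median-of-ratios and 0.02 after upper-quartile scaling, the 12 h value changed sign with upper-quartile scaling (-0.01), and the 24 h value was 0.20 after median-of-ratios and 0.18 after upper-quartile scaling. With a floor of 5 the 24 h value was 0.60, at a percentile of 68.2, over 3 members that passed that floor through their 24 h level. Family 5 had medians of 0.19 at 6 h, -0.01 at 12 h and 0.18 at 24 h. These were 0.14, -0.08 and 0.01 after median-of-ratios scaling and 0.12, -0.11 and -0.01 after upper-quartile scaling, and the 6 h median was 0.07 with a pseudocount of 5. In family 8.2, all 7 members were under 1 at 0 h, and the median level over them was 0.57 at 0 h and 1 at 24 h. Family 9.2 had 3 measured members that went apart: 2 were higher at 24 h, from 0.48 to 3.62 and from 0.94 to 3.88, and 1 had levels of 1.34 at 0 h and 0.96 at 24 h. Its median log2 ratio was 0.74 at 12 h and 1.33 at 24 h, at percentiles of 98.3 and 99.98, where the 12 h percentile was 96.99 with a pseudocount of 0.1 and 96.97 without matching. Both higher members were under 1 at 0 h and entered through their later level, and over all 6 members the median level was 0.285 at 0 h and 0.67 at 24 h.

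Among the letter codes, family VI had 4 measured members, all above their 0 h level at 24 h, with a median log2 ratio of 0.76 and levels of 2.93 to 5.96, against 1.66 to 2.74 at 0 h. Its percentile was 98.2 at 24 h, or 97.31 against random lists without matching, and 91.3 at 12 h, and at 6 h the median of 0.05 changed sign under either scaling. With pseudocounts of 0.1 and 5 the 24 h median of family VI was 0.95 and 0.40. In family IIIA, 5 of 28 members had levels of 0.10 to 0.47 at 0 h and 1.11 to 1.93 at 24 h. In this comparison they passed the floor through their 24 h level, so their ratios are not representative of the family, whose median level over all 28 members was 0.055 at 0 h and 0.15 at 24 h. The 3 genes coded Intron containing stood at 0.44 to 0.71 at 0 h, 0.48 to 0.72 at 12 h and 1.18 to 1.64 at 24 h, and they too passed the floor through their 24 h level. Differences of 2-fold at each time were found in 2 genes: 1 coded O had levels of 0.52 at 0 h, 3.09 at 6 h, 2.04 at 12 h and 2.35 at 24 h, and 1 coded Orphan had 0.53, 2.54, 2.81 and 2.64. After median-of-ratios scaling the gene coded O was under 2-fold at 12 h (log2 ratio 0.97) and 24 h (0.99), while that coded Orphan was over it at each time. The 4 measured members of family O went apart, with medians of 0.51, 0.43 and 0.43 at 6, 12 and 24 h, and over the same 4 members the 24 h median was 0.29 after median-of-ratios and 0.28 after upper-quartile scaling. Either scaling took 1 member under the floor, and the median of the other 3 was -0.18 and -0.20. Family ID, with 6 measured members at 6 and 24 h, had medians of 0.06, 0.05 and 0.19 at 6, 12 and 24 h, the first and second changed sign under either scaling, and the 24 h median was 0.03 after median-of-ratios and 0.01 after upper-quartile scaling. The largest code, IA, had 94 members, of which 5 were measured at 24 h, and the median level over all 94 was 0.07 at 0 h and 0.135 at 24 h. In all, 29 combinations of family and time had 3 or more measured members.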

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

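A search for genes with opposite directions at different times found 3 that were at least 2-fold lower than at 0 h at 6 h and at least 2-fold higher at a later time, all without a family code. Their levels followed one course: 22.01, 32.79 and 18.16 at 0 h, 7.96, 13.25 and 7.19 at 6 h, 40.60, 77.02 and 45.01 at 12 h, and 60.78, 100.16 and 61.19 at 24 h. The log2 ratios were -1.36, -1.25 and -1.23 at 6 h and 1.42, 1.58 and 1.70 at 24 h. Genes with one course may share reads, so these 3 may not be separate measurements. With 1 library per time the difference between times was not tested.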

How the results depend on the processing

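Upper-quartile scaling of the families and of the time of highest level was chosen after seeing the data. All counts of genes depended on the pseudocount, because it decides how far a gene near a level of 1 can move. With a pseudocount of 0.1 there were 539 higher and 152 lower genes at 6 h, 1714 and 630 at 12 h, and 2256 and 585 at 24 h, and with a pseudocount of 5 there were 92 and 19, 395 and 81, and 347 and 98. At a 4-fold threshold the counts were 21 and 2, 121 and 12, and 94 and 9. A floor of 5 left every count within 1.5 times. Removing the floor tests nothing here, since with a pseudocount of 1 a gene under the floor in both libraries cannot reach 2-fold. Median-of-ratios scaling moved the lower genes at 12 h to 406 and gave 633 higher and 645 lower genes at 24 h. Upper-quartile scaling gave 76 lower genes at 6 h, 494 lower at 12 h, and 586 higher and 705 lower at 24 h. Genes with a 4-fold range numbered 49, 36, 241 and 249 by highest level at 0, 6, 12 and 24 h with a pseudocount of 0.1, which turns the order of 12 and 24 h, and 7, 4, 37 and 18 with a pseudocount of 5. Those highest at 24 h were 35 with either scaling, and those highest at 6 h were 14 with upper-quartile scaling. Family 7 kept its direction with medians of 0.34, 0.59 and 0.59 at 6, 12 and 24 h after median-of-ratios scaling, 0.31, 0.54 and 0.56 after upper-quartile scaling, and 0.33, 0.53 and 0.68 with a pseudocount of 5. Family 6 had 0.53 at 24 h after median-of-ratios scaling, 0.14, 0.38 and 0.50 after upper-quartile scaling, and 0.32 at 12 h and 0.54 at 24 h with a pseudocount of 5. Its percentile at 6 h, 97.48, was 97.54 with median-of-ratios scaling, 97.97 with a pseudocount of 0.1, 97.91 with a floor of 5, 98.5 without matching, 97.83 with upper-quartile scaling and 97.44 with a pseudocount of 5. Over all families, 38 medians moved by more than the SD over members and 83 did not, and 8 percentiles crossed the central 95% of random lists while 142 did not. Scaling shifts a family and its matched lists alike. Percentiles under either scaling could therefore hardly change, except where scaling changed which members were measured, and they say little about robustness. The 4 genes printed by identifier kept their side of the 2-fold threshold in all 36 alternative values. Beyond what the pseudocount and the thresholds do by construction, the cause was not tested. No paired analysis was possible because each time had 1 library, and for the same reason no replicate could be left out. Depth limits the families of low level, since genes above 0 in 1 library only had a median level of 0.03 to 0.04.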

Other observations

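The tests of scaling, of age and of families 6 and 7 were chosen only after the result was seen, and the prediction for the levels of gene pairs was written before. No gene coded IE, IIA, IIB, IO, IV, Short, V or VII reached a level of 1, and the highest level among them was 0.62, in family IV at 24 h, where the median was 0.09 against 0.02 at 0 h. Family 1, with 43 members, also had none at 1 or above. Its median level was 0.25 at 0 h, 0.36 at 6 h, 0.30 at 12 h and 0.29 at 24 h. Across 19415 genes, the Pearson correlation of log2 levels was 0.978 between the 0 and 6 h libraries, 0.944 between 0 and 12 h and between 0 and 24 h, and 0.977 between 12 and 24 h. Genes are not independent replicates, so these values only rank the libraries by similarity.

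More genes were higher than lower at each time. If overall scaling between libraries were the cause, the share of higher genes should come to between 40 and 60% after median-of-ratios scaling. It was 49.5% at 24 h (45.4% with upper-quartile scaling), so scaling may account for the excess at that time. This support is weak, because the scaling centres the genes and so favours an even split. The share was 76.0% at 6 h (73.1%), which argues against scaling as the whole cause there. At 12 h it was 67.6%, but 60.7% with upper-quartile scaling, just over the range named. Arguing against scaling was taken to need an exact binomial interval over 60% under both scalings. Such an interval treats genes as independent, which they are not. Its lowest bound was 57.9% at 12 h, against 67.6% at 6 h, so scaling stays open at 12 h. Either scaling assumes that most genes do not change. Development cannot be told apart from exposure: genes 2-fold higher at 24 h were already higher at 12 h than at 6 h, by a median log2 of 0.513 against -0.03 to 0.04 in 1000 matched lists, but no unexposed library of a later time was compared.

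Members of families 6 and 7 differed from 0 h by nearly the same ratio. Neither scaling took the whole difference at 24 h away: the family medians stayed at 0.527 and 0.593 after median-of-ratios scaling and 0.50 and 0.56 after upper-quartile scaling. They lay over 0 by more than 2 SD over members, the bound set for arguing against scaling as the whole cause. Members that share reads would make this SD too small, so that bound carries little weight if they do. The SD over members was 0.108 in family 6 and 0.0728 in family 7, against 0.53 and 0.55 in typical matched lists. This restates the pattern and does not speak for either cause: reads shared between near-identical members and joint regulation of separate genes cannot be told apart without sequences.

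Sets of genes with one course over time stood at the top of the comparisons. Of the 9 genes with a 4-fold range that were highest at 6 h, 3 followed the course of the gene with the highest ratio within 0.4 on the log2 scale, a tolerance set after these genes were seen and wider than that for pairs. Among the 121 genes 4-fold higher at 12 h, 43 pairs matched within 0.15 at all 3 times. In 1000 shuffles the median was 30 and the highest 53. The ratios of each time were shuffled separately, which removes any link between times, and the rank of 43 was not taken. This count therefore does not speak for or against a cause. If reads shared between gene copies were the cause, matched pairs should have closer levels. Their median difference was 1.02 on the log2 scale, against 1.28 with shuffled levels (permutation p = 0.1, one-sided, 10000 permutations). Shared reads and chance matches therefore cannot be told apart with this number of pairs, and joint regulation was not tested. This p was at first counted as evidence against shared reads. It was read as leaving them open only after it was seen, because a missed threshold excludes nothing and the difference lay under the shuffled median.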
